A study of Mus musculus with 6 samples.

How the data were processed

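The data are RNA-seq libraries of mouse corneal endothelial cells, 3 from the Col8a2 mutant (Col8a2 group) and 3 from the Col8a2 mutant labelled Tcf4+/- (Tcf4+/- group). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with the RNeasy Micro Kit, full-length cDNA was made with the SMART-Seq HT Kit and libraries were prepared with Nextera XT, a protocol that is not described as keeping the strand. The labels do not say whether each library came from a separate animal or from pooled corneas, so p-values measure the spread between these samples, part of which may be technical.

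The deposited files give 1 row per Ensembl gene with estimated counts, TPM values, lengths and effective lengths, per the file headers. FastQC 0.12.1, fastp 0.23.2, STAR, RSEM and DESeq2 are named in the submitters' processing notes with genome build GRCm39, and the versions of the last 3 tools and the gene annotation release are not given in the sources used here. The expected counts deposited by the authors are not scaled to depth, and 9.97% of values are not whole numbers. The TPM values deposited by the authors are scaled to gene length and to the same sum in every library. Length minus effective length, which follows the mean fragment or read length used in the authors' estimate, was 211, 234 and 234 bases in the Col8a2 libraries and 241, 155 and 150 bases in the Tcf4+/- libraries.

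The files hold 57180 gene identifiers without names. Of these, 51933 were matched by identifier to a symbol in the GENCODE annotation M21 of build GRCm38 and 5247 were not. As the build differs from that of the files, this annotation was used only for names, gene types and which genes lie on the same chromosome or near each other, and no coordinates are given. RSEM shares reads among near-identical genes, so values of the hemoglobin, crystallin, histocompatibility and ribosomal protein genes and of pseudogenes are uncertain, and overlapping or antisense genes cannot be told apart without strand.

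Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, leaving 17639, scaled by TMM (factors from 0.973 to 1.06) and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust estimation, genotype group as the only term and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values are TMM-scaled, except those given for Xist and Ddx3y. The common biological coefficient of variation was 0.744 and the median standard error of a log2 fold change was 0.54, or 0.35 for genes of at least 10 TPM. With 3 against 3, an exact permutation test cannot give a p below 0.1, so the model p is given with the values of each library or mean ± SD. Intervals and floors that rest on counts cover counting error only. A gene at 0 in a whole group was set against a floor of 3 counts over the group.

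Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and adjustment over the 33 lists with at least 5 genes tested, out of 34 written (21 of function and 13 of markers). camera with an estimated correlation and fry were run beside it. Of the 7 lists that camera called, 0 were called with an estimated correlation. Lists with a member at 0 in a whole group, lens and cell cycle, have the same median, 4.15 and -0.51, with that member at its bound. The remaining list, of sex-linked genes, had 1 gene tested, Xist, with a log2 fold change of -0.33. Without TMM scaling, Xist was at 0.50 and 1.19 CPM in Col8a2 replicate 1 and Tcf4+/- replicate 3, where Ddx3y was at 36.7 and 33.4 CPM. In the other libraries Xist was at 45.3 to 84.8 CPM, so each group held 1 male pattern. The libraries of a group thus did not all come from the same animal.

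The genes named were set by a rule. It takes Tcf4 and Col8a2, then in each direction the 12 genes of largest change that pass the threshold with a mean of at least 1 TPM and no overlap between groups. With fewer than 5 such genes, the 12 of smallest unadjusted p under the same conditions are taken, leaving out unnamed and predicted genes, pseudogenes and ribosomal protein genes. In each list it takes up to 4 members past the threshold, else up to 3 past it adjusted over the list alone, else the 2 of smallest p, and in marker lists also the 2 of highest level. Of the genes this rule takes, 2 are not reported here. Tcf3, Tcf12, Lars2 and the genes of the closing observations were named after their values were seen.

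The scripts were tested on simulated counts with the real means, library sizes and dispersions and 200 changed genes in each of 5 runs. Of all genes tested, 1.60%, 37.2%, 60.8% and 68.8% were called at 2-fold, 4-fold, 8-fold and 16-fold, and of genes of at least 10 CPM 3.20%, 64.0%, 94.8% and 97.2%, and 4.38% of unchanged genes had an unadjusted p under 0.05. No pair of libraries had counts alike within sampling noise. Alternatives were DESeq2 size factors, upper-quartile scaling, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma voom with and without quality weights, edgeR without robust estimation, limma on log2 TPM with pseudocounts of 1 and 0.1, a replicate block, 1 surrogate variable from sva 3.50.0, sex as a covariate, removal of X and Y genes, protein-coding genes only, other thresholds and leaving out each library. Groups, tests, lists, the rule for named genes and these alternatives were fixed before the data were examined, with 1 exception. The test of genes around Tcf4 was planned on genes past the adjusted threshold and was run on the unadjusted p. Figures were drawn with matplotlib 3.10.9.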

Results

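RNA-seq was carried out on corneal endothelial cells, the layer that pumps fluid out of the cornea, from mice homozygous for a mutant Col8a2 allele. Col8a2 encodes a collagen chain of Descemet membrane, and this mutant is used as a mouse model of Fuchs endothelial corneal dystrophy. There were 2 groups of 3 libraries each, 1 from the Col8a2 mutant alone and 1 labelled as the Col8a2 mutant with a heterozygous knockout of Tcf4, an E protein transcription factor, as well. Total estimated counts ranged from 30344114 to 54265433 per library, and between 19635 and 22499 genes had a count. The comparison asked what loss of 1 Tcf4 allele changes in the endothelium of this model.

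Tcf4 itself was not lower in the libraries labelled Tcf4+/-. Its level was 404 ± 81.7 CPM (TMM-scaled counts relative to library size) in the Col8a2 group and 471 ± 116 CPM in the Tcf4+/- group (mean ± SD, n = 3 each). The libraries of the Col8a2 group stood at 313, 470 and 430 CPM, and those labelled Tcf4+/- at 440, 599 and 373 CPM, so the ranges overlapped. The fitted log2 fold change of Tcf4 (ENSMUSG00000053477) was 0.22 with a standard error of 0.33 and a 95% interval from -0.52 to 0.96, which is a fold of 1.17 with an interval from 0.698 to 1.95. The quasi-likelihood test of edgeR gave a Benjamini-Hochberg adjusted p of 0.99988, and the interval leaves out a log2 fold change of -1. These are counts over the whole gene, so a targeted allele that still gives a transcript is counted with the intact one. The sign of the Tcf4 change was negative, at -0.07, on the TPM scale (transcript abundance corrected for length), where the median of all genes tested lay at -0.19 to -0.21. On that scale mitochondrial tRNA genes took 15.6% and 15.8% of the total in Tcf4+/- replicates 2 and 3 and 0% elsewhere, which lowers the other genes there. Because Tcf4 did not show the loss that its label names, the groups are named below by their labels only.

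**Figure D1:**
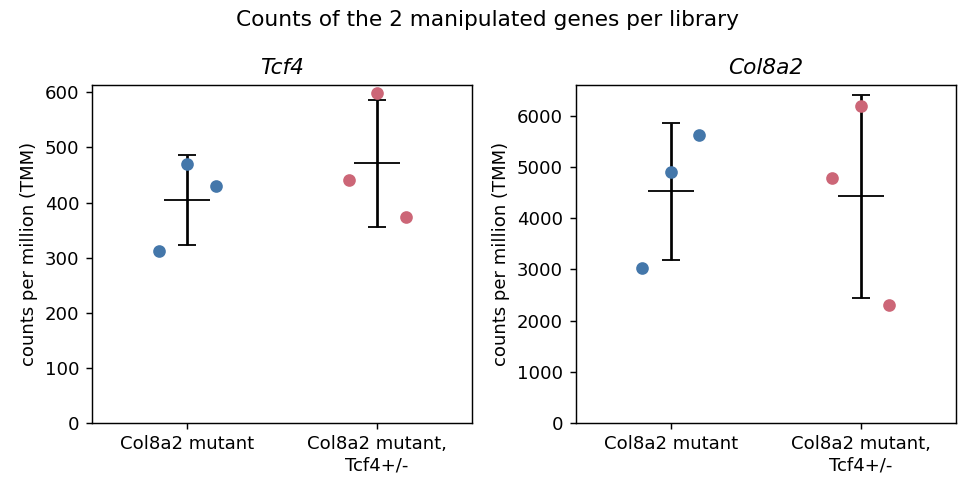
CPM (y axis, TMM-scaled counts relative to library size) of Tcf4 and Col8a2 in each library of the Col8a2 mutant group and the group labelled Tcf4+/-; points are libraries, horizontal bars are means and error bars are SD (n = 3 each). Tcf4 lies at 313 to 470 CPM in the first group and at 373 to 599 CPM in the second, and the groups overlap for both genes.

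Col8a2 transcripts were as abundant in one group as in the other within the spread. The level was 4529 ± 1344 CPM in the Col8a2 group and 4430 ± 1980 CPM in the Tcf4+/- group (mean ± SD, n = 3 each), with a log2 fold change of -0.03 and a standard error of 0.46. The sign of this difference changed under 8 of 24 other settings. Tcf3 and Tcf12, the other E proteins, stood at 47.1 ± 2.72 and 59.6 ± 7.75 CPM in the Col8a2 group and at 46.8 ± 7.96 and 57.1 ± 13.2 CPM in the Tcf4+/- group (mean ± SD, n = 3 each).

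No single gene passed the edgeR test between the groups. Of 17639 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 were lower at an adjusted p of 0.05, and 427 had an unadjusted p under 0.05, where 882 would by chance. Of these 427, 250 were fitted higher and 177 lower in the Tcf4+/- group. DESeq2 called 74 genes higher and 31 lower, and limma voom called 0. Of the 105 DESeq2 calls, 45 were genes at 0 in all libraries of 1 group, 85 had a mean under 5 CPM, and all 81 that edgeR also tested had an unadjusted edgeR p under 0.05. The values of the 3 libraries of a group did not overlap with those of the other for 1429 genes, or 8.10%, where chance gives 10%. With the spread of these libraries, simulated changes of 2-fold, 4-fold and 16-fold were called in 1.60%, 37.2% and 68.8% of cases over all genes tested. In genes of at least 10 CPM changes of 2-fold and 4-fold were called in 3.20% and 64.0%, so most changes of 2-fold would be missed here. The simulation drew each gene on its own, and 4.38% of its unchanged genes had an unadjusted p under 0.05. The share among the real genes was smaller, so the real test may call fewer changes than these simulated shares.

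None of the genes with the smallest p fitted lower in the Tcf4+/- group passed after adjustment with edgeR. DESeq2 called all of these 12 but Papss2 and Clcn5, with adjusted p from 3.48e-06 for Plaur to 0.0264 for Bcl3. The genes were chosen by smallest p from the same counts, so these calls are no separate support. In other splits of the 6 libraries into 3 and 3, DESeq2 called up to 192 genes. Plaur, the urokinase receptor, stood at 13.8 ± 9.37 CPM in the Col8a2 group and 1.02 ± 0.20 CPM in the Tcf4+/- group (mean ± SD, n = 3 each). Mthfd2, an enzyme of mitochondrial folate metabolism, stood at 21.4 ± 16.1 and 2.93 ± 1.28 CPM, and Lpin1, a phosphatidate phosphatase, at 26.9 ± 4.31 and 9.81 ± 0.86 CPM. Cdca3, a gene of cell division, stood at 10.1 ± 0.75 and 1.62 ± 0.56 CPM, and Bcl3, a member of the inhibitor of NF-kappaB family, at 30.6 ± 2.68 and 11.5 ± 3.24 CPM. Papss2, which makes the sulfate donor used on proteoglycans, stood at 48.2 ± 18.8 and 17.3 ± 5.03 CPM. The others chosen on this side were Cnfn, Pcdhb11, Clcn5, Klhl14, Zfp433 and Nmnat2, with log2 fold changes of -1.84, -3.83, -1.49, -3.37, -2.49 and -1.72. The unadjusted p of these 12 genes ran from 0.000468 for Plaur to 0.00765 for Nmnat2.

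None of the genes with the smallest p fitted higher passed after adjustment with edgeR either. DESeq2 called all of these 12 but Tstd2, with adjusted p from 2.92e-09 for Cpne6 to 0.0395 for Elobl. As on the lower side, the genes were chosen from the same counts, so these calls are no separate support. Cpne6, a copine, stood at 0.062 ± 0.043 CPM in the Col8a2 group and 6.87 ± 4.49 CPM in the Tcf4+/- group (mean ± SD, n = 3 each), and Ckmt2, the sarcomeric mitochondrial creatine kinase, at 0.155 ± 0.094 and 6.16 ± 3.23 CPM. Tbc1d22a stood at 12.9 ± 2.5 and 35.1 ± 3.13 CPM, the highest Tcf4+/- level of this set. Wdr66, Efhd1, Tmem25, Wdr17, Tstd2, Zfp54 and Elobl had log2 fold changes of 4.70, 4.43, 5.15, 3.44, 2.32, 3.67 and 2.40. The lens crystallin Crygd and the immunoglobulin gene Iglc2 had 0 counts in the Col8a2 group against 142 and 141 in the Tcf4+/- group. Set against a floor of 3 counts over the group, their pooled counts were at least 52.8-fold and 52.5-fold higher, for counting error only. The intervals of the fitted log2 fold changes, which take in the spread between libraries, began lower, at 3.52 for Crygd and 3.30 for Iglc2. The unadjusted p of these 12 genes ran from 0.000277 for Cpne6 to 0.00609 for Iglc2.

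The unfolded protein response list was called lower in the libraries labelled Tcf4+/- by camera with the preset correlation. The list had a median log2 fold change of -0.34, with 25 of 30 members fitted lower and 5 higher, and camera gave an adjusted p of 0.00419 over 33 lists. With an estimated correlation p was 0.208, so the call does not hold there. No member passed adjusted over the list alone, and 3 had an unadjusted p under 0.05. Creld2, a chaperone-like protein of the endoplasmic reticulum, stood at 140 ± 61.7 CPM in the Col8a2 group and 71.0 ± 28.7 CPM in the Tcf4+/- group, and Asns, asparagine synthetase, at 42.3 ± 16.9 and 20.6 ± 7.80 CPM (mean ± SD, n = 3 each). The mean log2 CPM of the list was 6.08, 6.49 and 6.07 in the Col8a2 libraries and 5.92, 6.14 and 5.57 in those labelled Tcf4+/-. The groups thus overlapped, as Tcf4+/- replicate 2 lay above Col8a2 replicates 1 and 3. Tcf4+/- replicate 3, the lowest, also had the lowest level of corneal endothelium markers, 7.89 against 8.54 to 9.19 in the others. Without Col8a2 replicate 2 the median was -0.19 (camera adjusted p = 0.129), and without Tcf4+/- replicate 3 it was -0.18 (adjusted p = 0.0773). Among fits chosen after seeing the data, the call was kept with the corneal endothelium level as a covariate, with a median of -0.27 (adjusted p = 0.00564), and lost with the lens level as a covariate, with a median of -0.09 (adjusted p = 0.392). In all, the call was kept under 21 of 24 alternatives with the preset correlation.

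The cell cycle list was also called lower, from a low level. Its mean log2 CPM was 3.26, 2.80 and 2.61 in the Col8a2 libraries and 2.48, 2.06 and 2.99 in those labelled Tcf4+/-. The groups thus overlapped, as Tcf4+/- replicate 3 lay above Col8a2 replicates 2 and 3. The median log2 fold change was -0.51 over 21 members, 15 of them fitted lower, with a camera adjusted p of 0.0359 and p = 0.202 with an estimated correlation. Aurkb, a kinase of chromosome segregation, passed adjusted over the list alone, with 444 counts in the Col8a2 group and 0 in the Tcf4+/- group. Against a floor of 3 counts over the group, its pooled counts were at least 133-fold lower, for counting error only. The interval of the fitted log2 fold change of Aurkb, which takes in the spread between libraries, reached up to -5.09, a smaller change. The camera call was lost without Col8a2 replicates 1 or 2 or Tcf4+/- replicates 1 or 2, with adjusted p of 0.146, 0.0924, 0.116 and 0.537 and medians of -0.0044, -0.29, -0.40 and -0.54. It was also lost with a mean of at least 5 CPM (median -0.35, adjusted p = 0.595) and on the TPM scales (medians -0.61 and -0.85, adjusted p = 0.146 and 0.197). Among fits chosen after seeing the data, it was lost with the lens level as a covariate (median -0.41, adjusted p = 0.0537). It was kept there with the corneal endothelium level (median -0.60, adjusted p = 0.00100). Without Tcf4+/- replicates 2 and 3, which leaves 1 library in the group, the median was -0.47. The call was kept under 15 of 24 alternatives, with the smallest adjusted p, 0.00073, and a median of -0.80 without Tcf4+/- replicate 3.

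Genes of the endothelial layer itself did not pass. The corneal endothelium list had a median log2 fold change of -0.10 (camera adjusted p = 0.391), the pump and transport list -0.16 (adjusted p = 0.195), the junction and adhesion list -0.10 (adjusted p = 0.305) and the collagens of Descemet membrane and matrix -0.03 (adjusted p = 0.433). Car3 and Ptgds, the endothelium markers of highest level by the rule, stood at 4709 ± 1370 and 2519 ± 1466 CPM in the Col8a2 group and at 5208 ± 678 and 1878 ± 345 CPM in the Tcf4+/- group (mean ± SD, n = 3 each). Gpc4 and Foxc1 of the same list had log2 fold changes of -0.70 and 0.31. Among transport genes, Cftr and Ano1 stood at 1.16 ± 1.35 and 9.92 ± 4.18 CPM in the Col8a2 group and at 0.079 ± 0.14 and 4.57 ± 3.49 CPM in the Tcf4+/- group. Nectin3 and Itga3 of the junction list had log2 fold changes of -1.16 and -0.81, and Col1a1 and Col4a2 of the collagen list 0.88 and -0.68.

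Matrix, transition and stress lists did not pass either. Matrix glycoproteins had a median log2 fold change of -0.18 (camera adjusted p = 0.150), and their members of smallest p were Timp1, an inhibitor of metalloproteinases, at -1.46 and the laminin chain gene Lama4 at 1.98. Targets of TGF-beta and of epithelial-mesenchymal transition had a median of 0.05 (adjusted p = 0.774), with Snai1 at 1.44 and Smad3 at -0.87; the direction camera gave for this list, lower, differs from its median. E proteins and their partners had a median of -0.01 and a mean of 0.05 (adjusted p = 0.774), with Atoh8 at -0.79 and Bhlhe40 at -0.54. The oxidative stress list stood at -0.05 (adjusted p = 0.150), and Sod3, the extracellular superoxide dismutase, at 1714 ± 409 CPM in the Col8a2 group and 829 ± 401 CPM in the Tcf4+/- group. Its other example, Slc7a11, had a log2 fold change of -1.19. The p53 and apoptosis list stood at -0.09 (adjusted p = 0.264), with Bcl2l11 at -1.08 and Bcl2l1 at -0.55, and the senescence list at -0.19 (adjusted p = 0.367), with Timp1 again and Lmnb1 at -1.14.

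Metabolic and other function lists showed no call by camera. Nuclear genes of oxidative phosphorylation had a median log2 fold change of 0.08 (adjusted p = 0.672), with Cox7c at 0.47 and Ndufb3 at 0.40. Mitochondrially encoded genes stood at 0.23 (adjusted p = 0.252), with mt-Nd6 at 0.58 and mt-Nd3 at 0.67. Glycolysis stood at -0.13 (adjusted p = 0.676), with Hk2 at 0.87 and Hk1 at 0.43, autophagy at -0.10 (adjusted p = 0.367), with Atg7 at -0.53 and Optn at 0.43, and cholesterol synthesis at -0.13 (adjusted p = 0.676), with Msmo1 at 0.42 and Srebf2 at -0.37. The interferon list stood at -0.41 (adjusted p = 0.0734), with Ifih1 at -0.93 and Oas1a at -1.21. Ribosomal proteins stood at 0.22 (adjusted p = 0.202), with Rpl37 at 0.72 and Rpl32 at 0.64, splicing factors at 0.23 (adjusted p = 0.604), with Tra2a at 0.54 and Ptbp1 at -0.53, and the Wnt list at 0.22 (adjusted p = 0.281), with Lef1 at 1.5 and Fzd2 at 0.61. Immediate early genes stood at 0.17 (camera adjusted p = 0.676), and fry's test for change in either direction gave an adjusted p of 0.0389 for this list. In it, Nr4a3 had 2 counts in the Col8a2 group and 237 in the Tcf4+/- group, a ratio of 132. The 95% interval of this ratio, for counting error only, ran from 36.2 to 1099. The interval of the fitted log2 fold change of Nr4a3, which takes in the spread between libraries, began lower, at 2.41. Nr4a3 did not pass adjusted over the list alone (edgeR adjusted p = 0.143). Socs3 had a log2 fold change of -1.18.

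**Figure D2:**
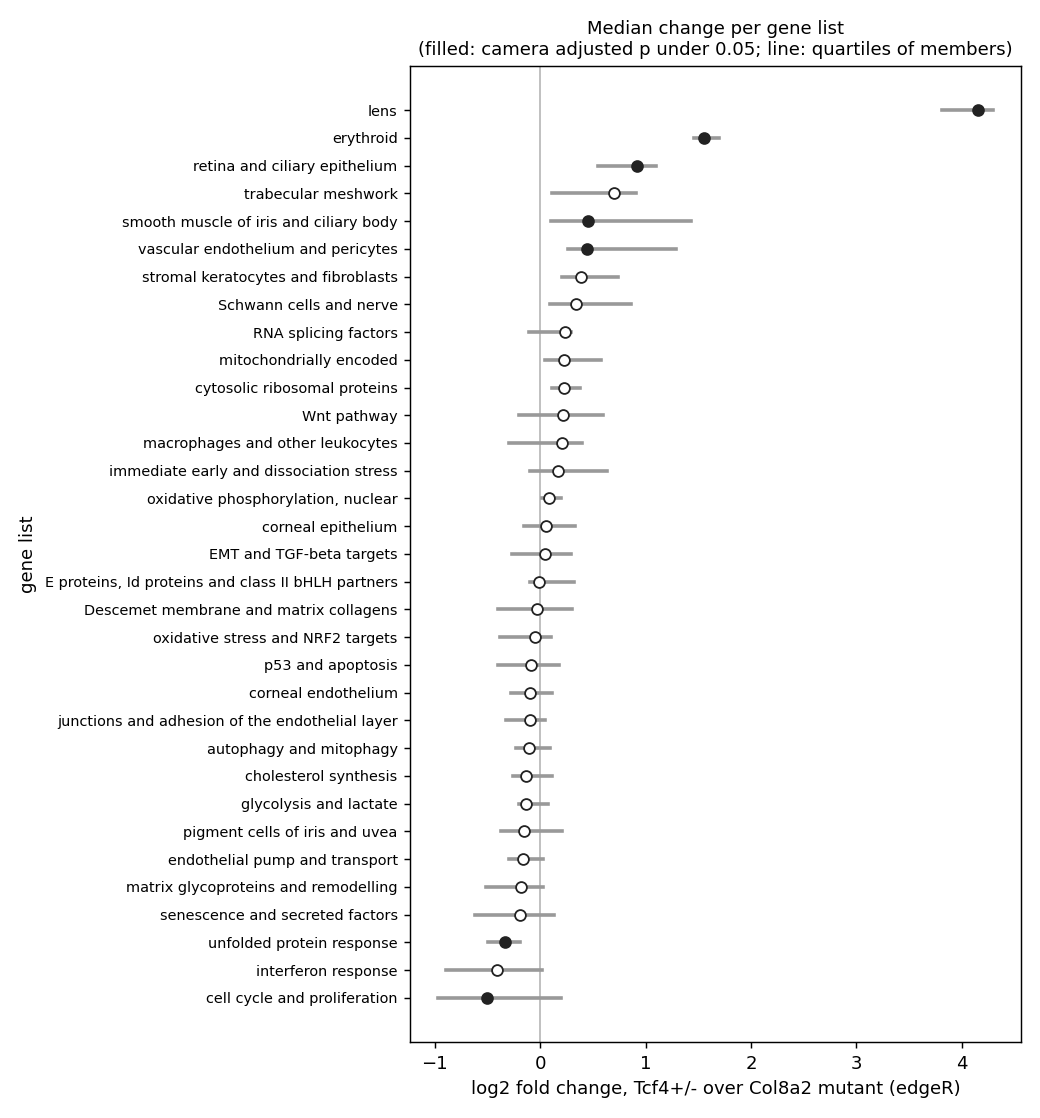
Median log2 fold change (x axis, Tcf4+/- over Col8a2 mutant) of the members of each of 33 gene lists (y axis); lines span the quartiles of the members, and filled points have a camera adjusted p under 0.05 with the preset correlation. The lens list stands apart at 4.15, and unfolded protein response and cell cycle lie at -0.34 and -0.51.

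Markers of the lens rose in the Tcf4+/- group, by way of replicates 2 and 3. The lens list had a median log2 fold change of 4.15 over 13 members (camera adjusted p = 2.56e-05, p = 0.185 with an estimated correlation), and 8 members passed adjusted over the list alone. Its mean log2 CPM was 6.83 and 7.72 in Tcf4+/- replicates 2 and 3, 2.82 in Tcf4+/- replicate 1, and 4.46, 1.74 and 3.81 in the Col8a2 libraries. Crybb2, a beta crystallin, stood at 91.1 ± 89.1 CPM in the Col8a2 group and 1724 ± 1698 CPM in the Tcf4+/- group (mean ± SD, n = 3 each), Crybb3 at 4.54 ± 3.37 and 89.2 ± 90.3 CPM, and Cryba4 at 6.94 ± 4.90 and 123 ± 116 CPM. Cryab, a crystallin also made outside the lens, stood at 677 ± 31.3 and 928 ± 476 CPM. The lens call was kept when each library was left out in turn, and under 22 of 24 alternatives. Leaving out 1 library always keeps Tcf4+/- replicate 2 or 3, so it cannot show whether the rise goes beyond these 2. The 2 alternatives that lost the call removed the lens level itself, as a covariate or by leaving out Tcf4+/- replicates 2 and 3, so the loss follows from their choice. The median was -0.29 with the covariate and -1.45 without these replicates, where 1 library is left in the group.

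**Figure D3:**
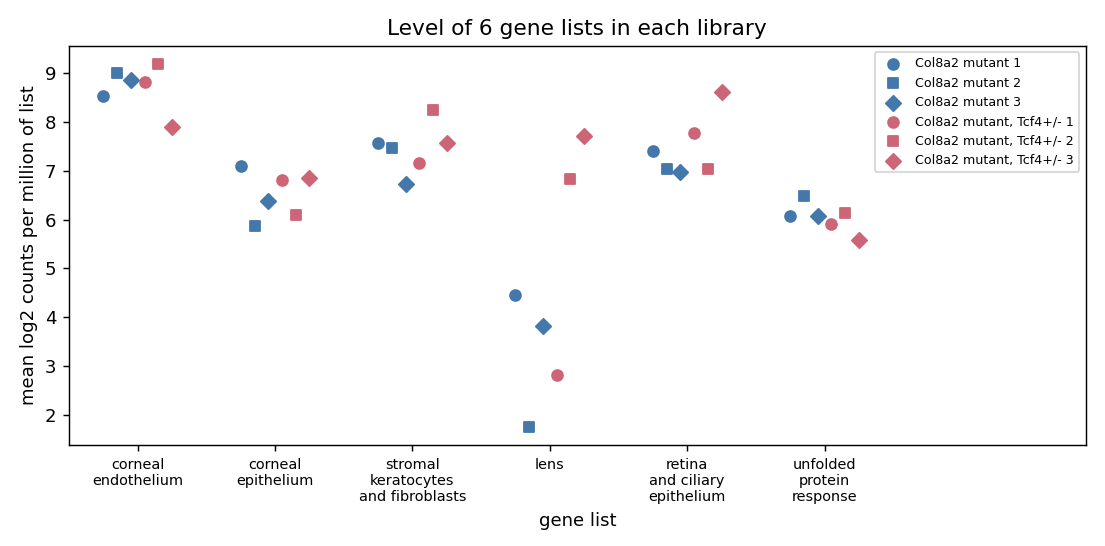
Mean log2 CPM (y axis) of 6 gene lists (x axis) in each of the 6 libraries; blue points are the Col8a2 mutant and red points the libraries labelled Tcf4+/-, with the replicate given by the shape. Lens markers reach 6.83 and 7.72 in Tcf4+/- replicates 2 and 3 and lie between 1.74 and 4.46 in the others, and corneal endothelium markers are lowest, at 7.89, in Tcf4+/- replicate 3.

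Markers of 4 further tissues were called higher with the preset correlation, and for each the groups overlapped in mean log2 CPM. For erythroid markers Tcf4+/- replicate 2 stood at 7.14, within the Col8a2 range of 5.58 to 7.70. The erythroid list had a median log2 fold change of 1.56 over 5 members (camera adjusted p = 0.00617, p = 0.188 with an estimated correlation), with Hbb-bs at 255 ± 121 CPM in the Col8a2 group and 749 ± 500 CPM in the Tcf4+/- group and Hba-a1, Hba-a2 and Hbb-bt at log2 fold changes of 1.35, 1.46 and 1.70. The call was lost without Col8a2 replicates 1 or 2 or Tcf4+/- replicates 1 or 3, with adjusted p of 0.0791, 0.129, 0.116 and 0.0773 and medians of 1.55, 1.22, 0.82 and 1.59, and was kept under 18 of 23 alternatives. Retina markers had a median of 0.92 (adjusted p = 0.0212, p = 0.273 with an estimated correlation). Gnat1, rod transducin, stood at 932 ± 143 CPM in the Col8a2 group and 1864 ± 1077 CPM in the Tcf4+/- group, and Opn1mw and Rcvrn had log2 fold changes of 2.5 and 1.24. The retina call was lost without Col8a2 replicates 2 or 3 or Tcf4+/- replicates 1 or 3, with adjusted p of 0.129, 0.215, 0.113 and 0.452 and medians of 0.84, 0.75, 1.05 and 0.28, and was kept under 19 of 24 alternatives. The mean log2 CPM of the retina list was 7.41, 7.04 and 6.97 in the Col8a2 libraries and 7.78, 7.05 and 8.61 in those labelled Tcf4+/-, so replicate 2 of the latter lay within the Col8a2 range.

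Smooth muscle of the iris and ciliary body had a median log2 fold change of 0.45 (camera adjusted p = 0.0312, p = 0.0557 with an estimated correlation), and vascular endothelium and pericytes 0.45 (adjusted p = 0.0420, p = 0.434 with an estimated correlation). Des and Actg2 had log2 fold changes of 1.36 and 3.22, and the abundant members Acta2 and Smtn 0.01 and 0.39. Plvap and Pecam1 had log2 fold changes of 1.85 and 1.57, and Egfl7 0.15. In mean log2 CPM, Tcf4+/- replicate 1 lay within the Col8a2 range for smooth muscle, at 3.73 against 3.24 to 3.77. For vascular markers only Tcf4+/- replicate 2, at 4.83, lay above the Col8a2 range of 1.98 to 3.93. The smooth muscle call was lost without Col8a2 replicates 1 or 3 or Tcf4+/- replicates 2 or 3, with adjusted p of 0.107, 0.305, 0.128 and 0.114 and medians of 0.58, 0.36, 0.34 and 0.38, and without Col8a2 replicate 2 it was kept with a median of 0.74. It was also lost without a filter (adjusted p = 0.0684), with DESeq2 (0.115) and with sex as a covariate (0.0526), where the medians stayed at 0.41, 0.42 and 0.46. The median fell to 0.28 with a mean of at least 5 CPM (adjusted p = 0.315). On the TPM scales it fell to 0.11 and 0.12 (adjusted p = 0.0790 and 0.113). The smooth muscle call was kept under 12 of 24 alternatives. The vascular call was lost without Col8a2 replicate 3 or Tcf4+/- replicates 2 or 3, with adjusted p of 0.940, 0.591 and 0.126 and medians of 0.19, 0.19 and 0.68. Without both of these Tcf4+/- replicates, a fit chosen after seeing the data that leaves 1 library in the group, the median was -0.45 (adjusted p = 0.719). The call was also lost with upper-quartile scaling (adjusted p = 0.0571), without a filter (0.0684) and with sex as a covariate (0.0789), with medians of 0.50, 0.44 and 0.48. Among fits chosen after seeing the data, the call was lost with the corneal endothelium level as a covariate (median 0.48, adjusted p = 0.0541). The same held with the lens level (median 0.27, adjusted p = 0.618). The vascular call was kept under 15 of 24 alternatives, with medians of 0.85 and 0.75 without Col8a2 replicates 1 and 2, and 1.38, 1.23 and 1.25 with limma voom, with quality weights and with the replicate block.

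Other cell types did not differ by the test. Keratocyte markers had a median log2 fold change of 0.39 (camera adjusted p = 0.0825), with Dcn and Lum at 0.49 and 0.84 and Dpt at 0.83. Trabecular meshwork markers stood at 0.70 (adjusted p = 0.0717), with Edn3 at 0.92, Tnmd at 1.66, Mgp at 0.91 and Angptl7 at -0.16. Corneal epithelium markers stood at 0.06 (adjusted p = 0.720), and Krt12 and Aldh3a1 were abundant in both groups, at 2713 ± 973 and 4143 ± 1672 CPM in the Col8a2 group and 2458 ± 2047 and 4059 ± 1155 CPM in the Tcf4+/- group (mean ± SD, n = 3 each). Krt15 and Krt14 had log2 fold changes of 0.75 and -0.65. Leukocyte markers stood at 0.21 (adjusted p = 0.636), with H2-Aa at 0.94, Cd74 at 0.77 and Lyz2 at -0.29, pigment cell markers at -0.15 (adjusted p = 0.774), with Slc24a5 at 0.47, Trpm1 at -0.33, Dct at 0.10 and Mlana at -0.02, and Schwann cell markers at 0.34 (adjusted p = 0.265), with S100b at 0.86 and Pmp22 at 0.17.

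Genes around Tcf4 on chromosome 18 did not stand out. Of 124 genes tested within 10 Mb of Tcf4, 0 passed the edgeR threshold, on which the test had been planned. An unadjusted p under 0.05 was found for 5, or 4.03%, against 2.41% of the other genes (two-sided Fisher's exact test, p = 0.23). On the whole chromosome, 15 of 461 genes had an unadjusted p under 0.05.

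Correlations between libraries overlapped within and between groups. Spearman correlations across genes ran from 0.908 to 0.912 within the Col8a2 group, from 0.901 to 0.940 within the Tcf4+/- group and from 0.880 to 0.941 between groups. The first principal component held 25.7% of the variance with values of -73.5, -68.0 and -9.03 in the Col8a2 group and -5.12, -0.64 and 156 in the Tcf4+/- group. The groups did not overlap on it, where chance gives 10% for 3 against 3, but they were separated only by the step from -9.03 to -5.12. They overlapped on components 2 and 3, which held 25.4% and 22.5% of the variance. On the first component Tcf4+/- replicate 3 lay farthest from the others. That library also had the highest level of Lars2, at 23559 CPM against 4771 to 9581 CPM in the others.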

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

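The values in this part were singled out after they were seen, and no test was planned for them. Mitochondrial tRNA genes were listed with 15.6% of all TPM in Tcf4+/- replicate 2 and 15.8% in Tcf4+/- replicate 3, against 0% in the Col8a2 libraries and in Tcf4+/- replicate 1. The libraries at 0% still held 2654 to 4778 estimated counts of these genes, so 0% of TPM does not mean that their RNA was absent. Of this, mt-Ts1 alone held 12.2% and 12.1%. TPM enters the alternatives on the TPM scale, the choice of genes to name and a summary of standard errors, and not the edgeR and camera tests. In estimated counts the same genes held 0.0197% and 0.0245% of the total in these libraries and 0.00517% to 0.00997% in the other libraries. Length minus effective length was 155 and 150 bases in the 2 libraries and 211 to 241 bases in the others.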

How the results depend on the processing

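The fits without Tcf4+/- replicates 2 and 3, with the lens level as a covariate and with the corneal endothelium level as a covariate were chosen after seeing the data. A value that passed no test was given no direction, so a change of sign among such values is not counted. Counts of 0 genes higher and 0 lower held under 24 of 26 alternatives each. DESeq2 gave 74 higher and 31 lower, with 4938 adjusted p not given by the tool, and the cause was not tested. Leaving out each library in turn gave 0 to 2 higher and 0 to 2 lower; the calls came without Col8a2 replicate 3, and were Pbp2 and Adh6a higher and Gbp2b and Rpl34-ps1 lower. The Tcf4 log2 fold change did not pass under any of 24 alternatives and ran from -0.07 to 0.36, with 0.02 to 0.36 when 1 library was left out. It was 0.12 without Tcf4+/- replicates 2 and 3, where that group is 1 library taken to vary as the others.

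Camera called 5 lists higher and 2 lower. Leaving out 1 library gave 1 to 6 higher and 0 to 5 lower. Of lists higher there were 3 without a filter on counts, 3 with sex as a covariate, 8 with limma voom, 2 without Tcf4+/- replicates 2 and 3, and 0 with the lens level as a covariate, with an estimated correlation or with fry. Of lists lower there were 1 with a mean of at least 5 CPM, 5 with quality weights, and 0 with the lens level as a covariate, with an estimated correlation or with fry. The cause was not tested. The unfolded protein response was called under 21 of 24 alternatives, with medians from -0.58 to -0.09 and adjusted p from 4.98e-05 to 0.392, the last with the lens level as a covariate. Lens was called under 22 of 24, retina under 19 of 24 and erythroid under 18 of 23. Cell cycle and vascular were called under 15 of 24 each and smooth muscle under 12 of 24.

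Replicate numbers did not pair the libraries: same-numbered libraries had correlations of deviations of -0.024, 0.139 and -0.015. With the replicate block, 0 genes were called higher or lower, 5 lists higher and 2 lower, and the Tcf4 log2 fold change was 0.21. At the same depth, a 2-fold change in genes of at least 10 CPM was called in 3.20% of simulated cases with the dispersion of these libraries and in 95.2% with 0.1 of it.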

Other observations

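The tests on other splits of the libraries and on genes around Adh6a were set before their results were seen, and the other tests in this part were chosen after.

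The samples held abundant transcripts of endothelium together with those of neighbouring tissues. Apoe stood at 10570 ± 4148 CPM in the Col8a2 group and 8836 ± 5967 CPM in the Tcf4+/- group, Igfbp2 at 7673 ± 1073 and 7009 ± 3850 CPM, and Npy, the gene of neuropeptide Y, at 1810 ± 116 and 1766 ± 779 CPM (mean ± SD, n = 3 each). Col8a1, which encodes the partner chain of Col8a2, was at 197 CPM in Tcf4+/- replicate 3 and at 701 to 1353 CPM in the other libraries. In the same library Gpc4 was at 103 CPM against 429 to 637 CPM in the others. Erythroid markers had their highest mean log2 CPM, 9.50, in Tcf4+/- replicate 1, where lens markers were at 2.82.

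Tcf4 was not lower in the libraries labelled Tcf4+/-. The tables argue against library scaling as the cause, since the lowest log2 fold change over 4 other scalings was -0.072. The 95% interval of the change began at -0.52, but counts over the whole gene say nothing of the allele, and a targeted allele whose transcript is still counted may give this. Tcf4 RNA from other cells also cannot be told apart here for the group as a whole. The sample titles give the Tcf4 genotype for the mice, so by label it is not limited to the endothelium. Relative to the endothelium markers, Tcf4 stood at 1.15 times the Col8a2 mean in the Tcf4+/- library richest in them and at 1.78 times in the poorest, so the outcome set for that cause and the one set against it were both met.

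Lens transcripts were higher in Tcf4+/- replicates 2 and 3 than in every Col8a2 library for 13 of 13 lens genes. A shorter read or fragment length in the same libraries cannot be told apart: abundant lens genes differed by a median of 7.04-fold between the highest and lowest of the other 4 libraries, but these hold none of the short ones. Lens RNA carried over at dissection may be the source, but its test did not come out for it: the SD of log2 ratios of 11 abundant lens genes between Tcf4+/- replicate 3 and Col8a2 replicate 1 was 1.38, above the bound of 1 set for a source of 1 profile, and above the SD of 88.7% of random gene sets. Between Tcf4+/- replicates 3 and 2 it was 1.03, and since lens parts need not share a profile the source stays open. For an effect of Tcf4 genotype, most lens genes were to have all Tcf4+/- libraries above all Col8a2 libraries. Only 1 of 13 had, so the outcome set against this cause was met. Tcf4+/- replicate 1, at a mean log2 CPM of 2.82, lay below Col8a2 replicates 1 and 3, at 4.46 and 3.81. As this rests on 1 library, an effect of genotype cannot be told apart either.

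Adh6a and Gbp2b, both on chromosome 3, were on or off by library and not by label, with 0 counts of Adh6a in Col8a2 replicates 1 and 2 and 3161 to 8025 in the others, and 1749 and 920 counts of Gbp2b in the former and 0 in the others. Pbp2 and Rpl34-ps1, both on chromosome 6, split the libraries in the same way, with 0 counts of Pbp2 in these 2 and 766 to 3835 in the others, and 4579 and 2661 counts of Rpl34-ps1 against 37 to 86. Depth is argued against, as the library with the fewest counts had 5083 counts of Adh6a, and an inherited segment shared by the 2 libraries was tested on 99 other genes within 10 Mb, of which 1 set them apart by at least 2-fold against 151 of 15028 genes elsewhere (Fisher's exact test, p = 1), and other pairs of libraries had up to 2 such genes. Both outcomes set against it beforehand were thus met, but they were too weak to exclude it, as the 95% interval of the odds ratio ran from 0.025 to 5.82 and counts of 0 to 2 cannot rank the pairs. An inherited segment stays open, strain background is not stated in the labels, and no other biological explanation was tested.

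The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. edgeR called 0 genes in the real split and at most 0 in another. With 0 in the real split, 10 of 10 splits must give as many, so this count decides nothing. Genes with an unadjusted edgeR p under 0.05 numbered 427 in the real split and 296 to 1159 in the others. Camera called 7 lists in the real split and up to 19 in another, and 7 of 10 splits gave as many. DESeq2 called 105 genes in the real split and up to 192 in another, and 6 of 10 splits gave as many. The split with 19 lists and 192 genes set Col8a2 replicates 1 and 2 with Tcf4+/- replicate 2 against the others, and another, of Col8a2 replicates 1 and 3 with Tcf4+/- replicate 1, gave 16 lists and 170 genes. The camera p of the lens list was as small as in the real split in 3 of 10 splits, the real one among them, and that of the unfolded protein response in 1 of 10, though with a bound of 0.001, chosen after seeing the values, 3 of 10 were under it for this list.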
